A study of Homo sapiens with 8 samples.

How the data were processed

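Total RNA of 4 myeloma cell lines, each cultured for 48 h at 21% or 1% oxygen, was labelled with Cy3 and hybridised to 8 one-colour Agilent arrays on 1 slide with 1 scan time, per the file headers and the labels. The lines were numbered 1 to 4 (RPMI8226, KMS12BM, KMS11, MM.1S). Nothing in the labels says that arrays came from repeated cultures, so p-values measure the spread between the 4 lines.

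The deposited scanner files hold spot intensity values on a linear scale, made with Agilent Feature Extraction 11.5.1.1 per the file headers: a processed signal, background-subtracted and not normalised between arrays, the median spot and local background intensities, and flags for spots well above background, saturated or outlying. A deposited table of the whole series holds log2 values, whose scale, found by setting its columns against the scanner files, is log2 of the processed signal less each array's 75th percentile, centred on each probe's median; the authors' own statement of that scale was not among the sources used here. The files name probes by transcript accession. Of 50599 probes, 29033 were matched to a current symbol of 20992 genes through the RefSeq table, and the other 21566 stay unnamed here. The array design was built on GRCh37 and the table on another assembly, so no coordinates are given.

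The main values were log2 of the processed signal minus each array's 75th percentile over non-control probes. Control spots and outlier spots were left out and spots of one probe averaged; no spot was saturated. A probe was tested if well above background on all 4 arrays of at least 1 oxygen group, which kept 19577. limma 3.58.1 (R 4.3.3) was fitted with cell line as a block (lmFit and eBayes, 3 residual and 4.13 prior degrees of freedom), and calls were made at a Benjamini-Hochberg adjusted p under 0.05 over the tested probes. The arrays of 1 line are paired because they come from the same line: their deviations from the group means correlated at 0.803 to 0.900. All folds are on the normalised log2 scale, with the error as the moderated SE.

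Except for BCL2L10, BNIP3 and EGLN3 at the end, the genes named were fixed by rule before the data were examined. They are the 15 genes with the largest rise and the 10 with the largest fall among those called, moved the same way in 4 of 4 lines, well above background on all 8 arrays and with a gene symbol; up to 6 called genes measured in 1 group only, of which MINDY4 alone met the rule; up to 4 members of each gene list with the smallest adjusted p; a fixed set of genes of hypoxia, apoptosis and plasma cells; and translocation genes per line. Some genes that the rule takes are not reported here, and counts of genes include them. A gene stood for its tested probe with the highest mean. Of 35 named genes with several tested probes, none had probes called in opposite directions and 5 had some probes called and some not. The 33 gene lists were also fixed beforehand. The 29 with at least 5 tested genes were tested with camera (preset correlation 0.01, then estimated) and fry, each with Benjamini-Hochberg adjustment over the lists. For description, each list's median was set beside 10000 random lists matched on mean signal. Where a gene was not well above background on any array of a group, "at least" folds compare the bright group's mean with, per array, the higher of the lowest signal well above background and the probe's own. Single values were compared by an exact test over the 16 sign flips of 4 pairs.

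The fit was tested on simulated data for this comparison (19556 probes, 200 of them changed, 10 draws for each of 2 ways to set the variances). With variances drawn from the fitted prior it called 89.8% of probes changed by 2 on the log2 scale, 19.6% of those changed by 1 and 0.7% of those changed by 0.5, with 2 to 7 false calls a draw (5.7% of all calls). With each probe's own moderated variance it called 99.5%, 56.3% and 1.0%, with 4 to 21 false calls a draw (9.6% of all calls, above the 5% aimed at). In the data 4523 probes were called, far more than the 200 changed in a draw. The adjusted threshold depends on that share, so these detection rates need not hold for the data. Alternatives were normexp correction, quantile normalization, median centring, no filter and a stricter one, outlier spots kept, the deposited log2 table, no block, trended robust moderation, array weights, 1 probe per gene and each line left out. Normexp was planned on mean spot signals and run on median ones, which the files hold. Slide row as a further term was added after the data were seen. Random numbers were seeded, and Python 3.11.15 with pandas 2.3.3 read the files.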

Results

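Gene expression was measured in 4 human multiple myeloma cell lines, which are cultured malignant plasma cells, after 48 h at 21% oxygen (normoxia) or 1% oxygen (hypoxia). The lines were RPMI8226 (replicate 1), KMS12BM (replicate 2), KMS11 (replicate 3) and MM.1S (replicate 4). Each line gave 1 array per condition, so that each oxygen group held 4 arrays and the lines were the replicates. The 75th percentile of the processed signal was lower under hypoxia in 4 of 4 lines, with a mean of 558 ± 181 (SD, n = 4) under normoxia and 356 ± 52.4 (SD, n = 4) under hypoxia; the exact sign-flip permutation test gave a two-sided p of 0.125, the smallest that 4 pairs allow. Probes well above background made up 49.6% ± 4.87 (SD, n = 4) of the probes under normoxia and 47.7% ± 1.39 (SD, n = 4) under hypoxia (exact p = 0.375). The number of arrays limits the precision of every value.

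The stated purpose of the series was to find genes that protect myeloma cells from apoptosis, by comparing each line under hypoxia with the same line under normoxia. The median change of glucose use genes and of known targets of the hypoxia-inducible factors lay above 0 in each of the 4 lines, and that of DNA replication and cell division genes below 0. Among genes called and well above background on all 8 arrays, the largest rise was that of PFKFB4, an enzyme that controls the rate of glycolysis, at 10.0-fold (log2 change 3.32, SE 0.40, adjusted p = 0.0093, higher in 4 of 4 lines). In the same set the largest fall was that of GINS2, a subunit of the replicative helicase, which was 4.64-fold lower (log2 change -2.22, SE 0.33, adjusted p = 0.011, lower in 4 of 4 lines). Of 19577 probes tested with limma, with cell line as a block, 1339 were higher and 3184 lower under hypoxia at an adjusted p under 0.05. Of these, 1317 and 3171 moved the same way in all 4 lines, and 445 and 891 changed at least 2-fold. With each array centred on its median in place of its 75th percentile, 1848 probes were higher and 2314 lower (44.4% of calls higher, against 29.6%), and that scaling moved the median log2 change of all tested probes by 0.10; 589 were then at least 2-fold lower. Quantile normalization gave 1727 lower probes (577 at least 2-fold), normexp correction 186 that were at least 2-fold higher, and 1 probe per gene 664 higher (213 at least 2-fold). No probe was called when dim probes were not filtered (8894 of 50550 probes had an unadjusted p under 0.05) or when the cell line was left out of the model (1450 of 19577). With 1 line left out, 844 higher and 1749 lower probes were called without RPMI8226, 241 and 560 without KMS12BM, 467 and 1312 without KMS11, and 818 and 2043 without MM.1S. Calls were fewest without KMS12BM, so a call that ended there need not rest on that line. With the slide row of each array as a term, chosen after the data were seen, 819 higher and 1789 lower probes were called; MM.1S alone separates row from oxygen in that fit.

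Of 29 gene lists with at least 5 tested genes, 9 were higher and 7 lower than the other tested genes by the camera test with a preset correlation. None passed with an estimated correlation, and 12 passed by fry. Camera with an estimated correlation rests on the 3 residual degrees of freedom. It thus has little power here, and failing it is weak evidence against a list. Another split of the arrays that parted every line put 17 lists past the camera test, against 16 for the real one. It exchanged the arrays of KMS11 alone and so still largely compared the oxygen groups. Splits that parted every line and were balanced for oxygen put 4 to 7 lists past the test. A small camera p-value of a list below can thus arise without oxygen. The counts of called members come from the test of each probe. Over all 11573 tested genes, with 1 probe each, 586 were called higher and 2361 lower, and list counts are to be read against these. Camera sets a list against the other tested genes, so its direction is relative to them and not to 0. With 1 probe per gene the median log2 change of all tested genes was -0.179. For oxygen sensing, unfolded protein response and erythroid genes the median and mean change lay below 0 while camera gave the direction as higher. For autophagy and pro-apoptotic genes the median alone lay below 0, and for anti-apoptotic genes, p53 targets and long noncoding RNAs the mean alone, with camera again giving higher.

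Targets of the hypoxia-inducible factors, the transcription factors that accumulate when oxygen is low, were the list with the largest median rise. The array held 30 members, of which 18 were tested. Of these, 13 rose, none fell and 5 did not pass the test (16 rose when adjusted over the list alone), with a median log2 change of 1.74. With no filter, which admits dim probes, the median was 1.38. P4HA1, a collagen prolyl hydroxylase, rose 4.84-fold (log2 change 2.28, SE 0.21, adjusted p = 0.0081). NDRG1 rose 5.42-fold (SE 0.29 on the log2 scale, adjusted p = 0.0093) and the transcription repressor BHLHE40 3.54-fold (SE 0.25, adjusted p = 0.010). VEGFA, the main growth factor of blood vessels, rose 3.33-fold (SE 0.26, adjusted p = 0.011). DDIT4, an inhibitor of mTOR signalling, rose 6.14-fold (SE 0.44, adjusted p = 0.013), and its log2 change ranged from 0.85 in KMS11 to 3.80 in KMS12BM. ANKRD37 rose 4.00-fold and HILPDA, a lipid droplet protein, 3.63-fold, although the call for ANKRD37 ended without KMS12BM and that for HILPDA without KMS12BM or KMS11 and with slide row as a term; without RPMI8226 the log2 change of HILPDA was 1.22 against 1.86. CA9, a carbonic anhydrase, was well above background on 1 normoxia array and 2 hypoxia arrays and was not tested. The camera test of the list gave an adjusted p of 1.1e-13 with a preset correlation and an adjusted p of 0.35 with an estimated correlation.

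Of 23 tested genes of glycolysis and glucose uptake, 11 rose, none fell and 12 did not pass (14 higher and 1 lower when adjusted over the list alone), with a median log2 change of 0.77. PFKFB3, a second enzyme of the PFKFB4 family, rose 3.14-fold (log2 change 1.65, SE 0.20, adjusted p = 0.0093). The aldolase ALDOC rose 3.03-fold (SE 0.24 on the log2 scale, adjusted p = 0.011) and the lactate exporter SLC16A3 rose 3.81-fold (SE 0.35, adjusted p = 0.015). PDK1, which restrains entry of pyruvate into the tricarboxylic acid cycle, rose 1.93-fold (SE 0.22, adjusted p = 0.025) and the lactate dehydrogenase subunit LDHA 1.57-fold (SE 0.17, adjusted p = 0.038). The call for LDHA ended without any 1 of the 4 lines and under quantile normalization, and that for PDK1 without RPMI8226, KMS12BM or KMS11 and with slide row as a term. The camera test gave an adjusted p of 2.1e-10, and an adjusted p of 0.14 with an estimated correlation.

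Other genes of the 15 largest rises were CFAP96 (5.59-fold, SE 0.19 on the log2 scale), the cell cycle inhibitor CDKN1C (4.77-fold, SE 0.29), the matrix protein EFEMP2 (4.37-fold, SE 0.30) and the amino acid oxidase IL4I1 (4.25-fold, SE 0.39). IL17C, a cytokine, rose 3.79-fold (SE 0.18) and TEX19 3.60-fold (SE 0.35). RNA5-8SN5, a ribosomal RNA, rose 3.79-fold with a wide spread between lines (log2 changes of 0.23 in RPMI8226 and 3.47 in KMS11), and its call ended without KMS12BM, KMS11 or MM.1S and with slide row as a term. CAND1.11 rose 3.62-fold (SE 0.37). The call for CAND1.11 ended without KMS11 and with slide row as a term, and that for TEX19 without RPMI8226.

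**Figure D1:**
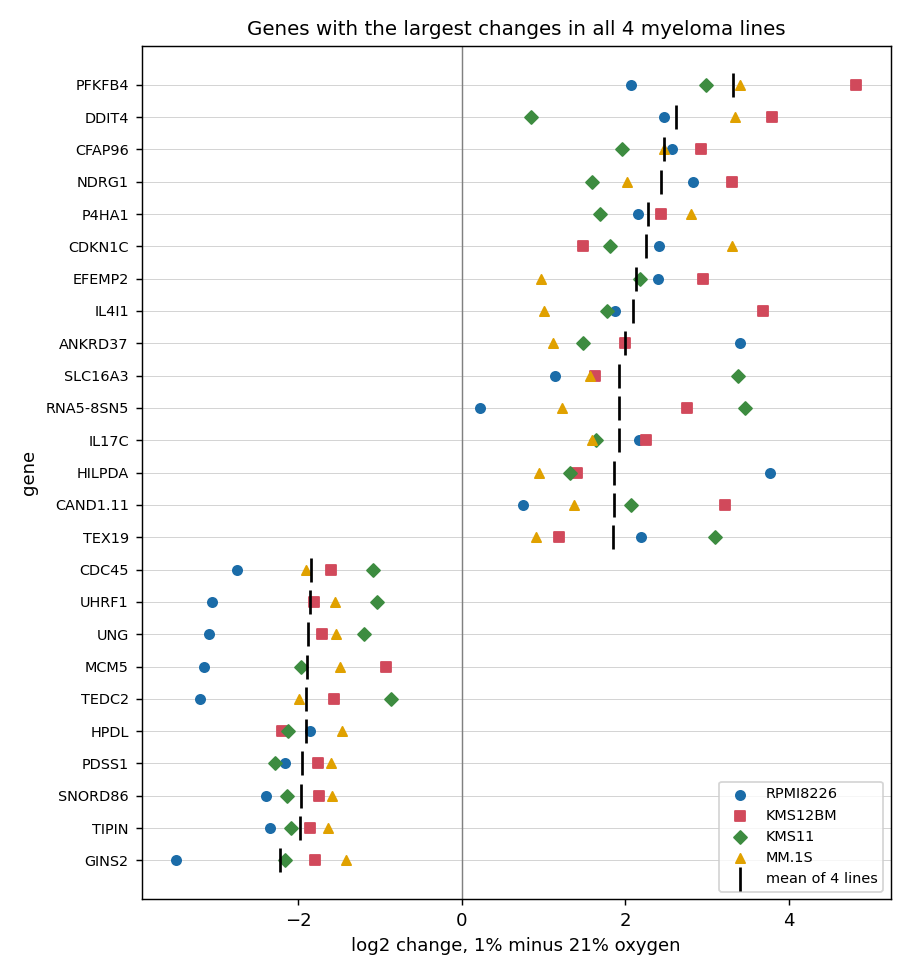
Log2 change between 1% and 21% oxygen (x axis) of the 15 genes with the largest rise and the 10 with the largest fall among genes called, well above background on all 8 arrays and moved the same way in all 4 lines (y axis). Points are the 4 lines, 1 array per line and condition, and black bars are the means of 4 lines, from 3.32 for PFKFB4 to -2.22 for GINS2.

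All 24 tested DNA replication genes fell under hypoxia, with a median log2 change of -1.51 against -0.27 for random lists matched on mean signal. MCM5, a subunit of the replicative helicase, was 3.69-fold lower (log2 change -1.89, SE 0.34, adjusted p = 0.014) and CDC45, which works with it, 3.57-fold lower (SE 0.26, adjusted p = 0.011). The sliding clamp PCNA was 3.24-fold lower (SE 0.24, adjusted p = 0.011) and UHRF1, which keeps DNA methylation through replication, 3.63-fold lower (SE 0.31, adjusted p = 0.013). Outside the list, TIPIN, a replication fork protein, was 3.95-fold lower (SE 0.17) and the uracil-DNA glycosylase UNG 3.69-fold lower (SE 0.30). Also among the 10 largest falls of genes well above background on all 8 arrays were SNORD86 (3.92-fold lower, SE 0.18), PDSS1, an enzyme of coenzyme Q synthesis (3.87-fold, SE 0.17), HPDL (3.76-fold, SE 0.18) and TEDC2 (3.75-fold, SE 0.35). Of the cell proliferation genes, mostly genes of mitosis, 20 of 22 fell and 2 did not pass (22 fell when adjusted over the list alone); CCNA2 was 2.86-fold lower (SE 0.16, adjusted p = 0.0090) and CCNB1 2.77-fold lower (SE 0.15, adjusted p = 0.0090). Genes of homologous recombination and mismatch repair fell in 13 of 17 cases (14 over the list alone), with XRCC3 3.21-fold lower (SE 0.20) and RAD51C 2.52-fold lower (SE 0.22). Of 24 MYC target genes, many of them ribosome assembly factors, 16 fell, 1 (LDHA) rose and 7 did not pass (19 lower and 1 higher over the list alone), with the polyamine enzyme SRM 3.13-fold lower (SE 0.21) and NOP56 2.43-fold lower (SE 0.16). MYC itself had a log2 change of -0.33 (SE 0.18, adjusted p = 0.22). The camera test gave adjusted p-values of 9.8e-10 for replication, 1.7e-08 for proliferation, 1.3e-05 for repair and 1.1e-05 for MYC targets. With an estimated correlation the adjusted p was 0.45 for replication, 0.47 for proliferation, 0.50 for repair and 0.45 for MYC targets.

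Of 28 respiratory chain genes, 16 fell and none rose (22 fell over the list alone), with a median log2 change of -0.59; CYC1 was 1.99-fold lower (SE 0.14, adjusted p = 0.010). Of 23 genes of the tricarboxylic acid cycle, 14 fell and none rose (14 over the list alone), with a median of -0.70; DLAT was 2.34-fold lower (SE 0.16, adjusted p = 0.0094) and fumarate hydratase (FH) 2.19-fold lower (SE 0.17, adjusted p = 0.011). Of 14 heat shock proteins, 10 fell and none rose (12 over the list alone), with HSPH1 2.70-fold lower (SE 0.22) and HSP90AA1 2.03-fold lower (SE 0.16). Random lists matched on mean signal had median changes of -0.35, -0.28 and -0.26 for these lists, and 238, 1 and 0 of 10000 such lists lay at or below the list. Under quantile normalization the median was -0.37 for the respiratory chain and -0.45 for the cycle. The camera test gave adjusted p-values of 1.0e-05 for the respiratory chain, 0.0011 for the cycle and 0.00015 for heat shock proteins. With an estimated correlation the adjusted p was 0.35 for each of them.

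Of 18 oxidative stress genes, 5 fell (6 over the list alone), among them mitochondrial SOD2, which was 2.38-fold lower (SE 0.18, adjusted p = 0.011), and the camera test did not pass (adjusted p = 0.51) except with no filter (0.027). With no filter the median log2 change of all probes was 0.244, against -0.074 in the main fit. Lists that passed only with no filter were thus set against higher values. By fry the oxidative stress list passed (adjusted p = 0.028). Of 19 genes of the integrated stress response and amino acid supply, 5 fell (8 over the list alone), with the serine synthesis enzyme PSAT1 2.72-fold lower (SE 0.27, adjusted p = 0.015, a call that ended without KMS12BM). That list did not pass (adjusted p = 0.099) but did without RPMI8226 (0.00014), with no filter (0.0056), with array weights (0.029) or with slide row as a term (0.042); its median was 0.16 in RPMI8226 and -0.97 in KMS12BM. Of 21 cholesterol genes, 3 fell (3 over the list alone), with NSDHL 1.91-fold lower (SE 0.18, adjusted p = 0.016, a call that ended without KMS11 and under quantile normalization); the list did not pass (adjusted p = 0.087) but did without RPMI8226 (0.0022) or KMS12BM (0.019), with no filter (0.0042), with slide row as a term (0.00064) and after normexp correction (0.037). Its median was 0.21 in RPMI8226 and -1.37 in MM.1S. Of 21 genes of the unfolded protein response, 5 fell (5 over the list alone), with SDF2L1 1.86-fold lower (SE 0.17, adjusted p = 0.016, a call that ended without KMS12BM), and the list did not pass (adjusted p = 0.84).

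The genes nearest to the purpose of the series moved in both directions. Of 16 anti-apoptotic genes, BCL2 rose and 3 fell (1 and 3 over the list alone). BCL2 was 1.64-fold higher (log2 change 0.71, SE 0.19, adjusted p = 0.038, higher in 4 of 4 lines), and the call ended when any 1 line was left out. MCL1 had a log2 change of 0.58 (SE 0.19, adjusted p = 0.063) and BCL2L1 of 0.26 (SE 0.20, adjusted p = 0.36). API5 and AVEN were 1.79-fold (SE 0.21) and 1.76-fold (SE 0.21) lower, and both calls ended without RPMI8226, KMS12BM or KMS11, with slide row as a term and under quantile normalization. A further API5 probe was not called (log2 change -0.62, adjusted p = 0.085). BIRC5, an inhibitor of apoptosis that also acts in cell division, was 2.45-fold lower (SE 0.20, adjusted p = 0.011). Of 20 pro-apoptotic genes, 4 rose and 4 fell (5 and 4 over the list alone). In both lists the share that fell was near that over all tested genes (2361 of 11573). Over all tested genes 586 of 11573 rose, a share near that of the anti-apoptotic genes (1 of 16). The share of pro-apoptotic genes that rose (4 of 20) was larger, and the difference was not tested. BNIP3L rose 3.46-fold (SE 0.35, adjusted p = 0.017), BCL2L11 2.11-fold (SE 0.20, adjusted p = 0.015) and BMF 1.86-fold (SE 0.14, adjusted p = 0.012), whereas cytochrome c (CYCS) was 2.36-fold lower (SE 0.20, adjusted p = 0.012). Each of these 4 calls ended without KMS12BM, and 1 of the 3 BCL2L11 probes was not called (log2 change 0.06, adjusted p = 0.81). Of 14 p53 targets, BTG2 and BBC3 were called higher and FAS lower (2 and 1 over the list alone), and each of these calls ended without RPMI8226, KMS12BM or KMS11 and with slide row as a term. The camera test passed for none of these 3 lists (adjusted p = 0.30, 0.29 and 0.24).

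KDM3A, a histone demethylase that needs oxygen for its reaction, rose 3.35-fold (log2 change 1.74, SE 0.17, adjusted p = 0.0088), with log2 changes of 1.82 in RPMI8226, 1.93 in KMS12BM, 1.29 in KMS11 and 1.94 in MM.1S. Of 18 JmjC demethylases and TET enzymes, 4 rose and 1 fell (4 and 1 over the list alone), with a median of 0.10 that ranged from 0.00 to 0.20 over settings. KDM4B rose 2.09-fold (SE 0.19, adjusted p = 0.015, a call that ended without KMS12BM), and RIOX1 was 2.12-fold lower (SE 0.17, adjusted p = 0.012). The camera test gave an adjusted p of 0.025, with an adjusted p of 0.45 under an estimated correlation and of 0.067 without RPMI8226, 0.054 with array weights and 0.15 with no filter. By fry this list did not pass (adjusted p = 0.16). Of 16 genes of the oxygen sensing machinery, EGLN1, a prolyl hydroxylase that marks the hypoxia-inducible factors, rose 2.44-fold (SE 0.25, adjusted p = 0.017, a call that ended without KMS12BM), and ELOC and ELOB were called lower (1 higher and 1 lower over the list alone; both calls ended under quantile normalization and without KMS12BM or KMS11), and the list did not pass (adjusted p = 0.51). HIF1A had a log2 change of -0.37 (SE 0.25, adjusted p = 0.31), and EPAS1, well above background on 3 arrays of each group, was not tested. The transcription factor KLF2 was 2.31-fold lower (SE 0.31, adjusted p = 0.035), with log2 changes of -2.29 in RPMI8226 and -0.21 in KMS12BM; its call ended without RPMI8226, KMS11 or MM.1S, under quantile normalization, with array weights and with slide row as a term. IRF4, a transcription factor of plasma cells, had a log2 change of -0.52 (SE 0.29, adjusted p = 0.22) with values of 0.11 in RPMI8226 and -1.60 in KMS11. Of 16 plasma cell identity genes, PIM2 was called higher (a call that ended without any 1 line), KLF2 lower and 14 were not called (no call over the list alone), with an adjusted p of 0.93 for the list. SDC1 had a log2 change of -0.49 (SE 0.22, adjusted p = 0.15) and the chemokine receptor CXCR4 of 0.20 (SE 0.19, adjusted p = 0.47).

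Of 7 genes of matrix modification, P4HA1 and PLOD1 rose (2 over the list alone), PLOD1 2.41-fold (SE 0.15, adjusted p = 0.0093). Of 8 angiogenic factors, VEGFA and SEMA4D rose (4 over the list alone). SEMA4D lost its call without KMS12BM, KMS11 or MM.1S, and its other probe was not called (log2 change 0.07, adjusted p = 0.85). Of 10 adhesion and homing genes, CCR10 and SELPLG were called higher and HMMR lower (3 and 1 over the list alone), and none of the 3 calls held without KMS12BM. Of 13 NF-kB targets, TRAF1 rose (1 over the list alone), by 3.31-fold (SE 0.20, adjusted p = 0.0093), and of 14 interferon-stimulated genes IFI6 was called higher (none over the list alone), a call that ended without RPMI8226, KMS12BM or KMS11 and with slide row as a term. The interferon list had a median of 0.24, with -0.62 in RPMI8226, -0.10 in the fit without MM.1S, 0.42 without RPMI8226, 0.41 with slide row as a term, 0.13 with array weights and 0.04 after normexp correction, and fry gave an adjusted p of 0.66. The NF-kB list had a median of 0.46, with 0.17 without RPMI8226, 0.25 with array weights and 0.24 with slide row as a term, and fry gave an adjusted p of 0.16. Medians were 0.36 for matrix genes (0.54 without KMS11), 0.85 for angiogenic genes (0.50 without RPMI8226) and 0.23 for adhesion genes (0.45 under quantile normalization, 0.14 after normexp correction). The camera test gave adjusted p-values of 0.0011 for matrix, 0.0035 for angiogenic, 0.038 for adhesion, 0.0018 for NF-kB and 0.045 for interferon genes. With an estimated correlation the adjusted p was 0.35 for matrix, angiogenic and adhesion genes, 0.45 for NF-kB and 0.53 for interferon genes. By fry the adjusted p was 0.018 for matrix, 0.026 for adhesion and 0.057 for angiogenic genes. The adhesion list did not pass without KMS12BM, KMS11 or MM.1S (adjusted p = 0.059 to 0.076), after normexp correction (0.057), with no filter (0.25) or without the cell line block (0.22). The interferon list did not pass without KMS12BM or MM.1S (adjusted p = 0.15 and 0.34), after normexp correction (0.11), under median centring (0.062), with no filter (0.24) or without the block (0.12). None of 24 ribosomal protein genes was called (none over the list alone), with a median of 0.18 against 0.19 for lists matched on signal. The list median was 0.03 under quantile normalization, 0.10 after normexp correction and 0.28 under median centring. The camera adjusted p was 4.9e-05, with an adjusted p of 0.51 under an estimated correlation and of 0.40 after quantile normalization. Ribosomal protein genes did not pass by fry (adjusted p = 0.085). Of 12 autophagy genes, BNIP3L rose (1 over the list alone; camera adjusted p = 0.29). Of 14 long noncoding RNAs, MALAT1 was called higher and DANCR and SNHG1 lower (1 and 2 over the list alone; camera adjusted p = 0.24), and none of the 3 calls held without KMS12BM. MALAT1 was 1.51-fold higher at its brightest tested probe (SE 0.16, adjusted p = 0.041), with 5 of its 8 tested probes called higher and 3 not called. The other called probes had log2 changes of 0.95 to 1.24, and those not called of -0.16 to -0.07. The call at the brightest probe also ended without RPMI8226 or KMS11, under quantile normalization and with slide row as a term.

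**Figure D2:**
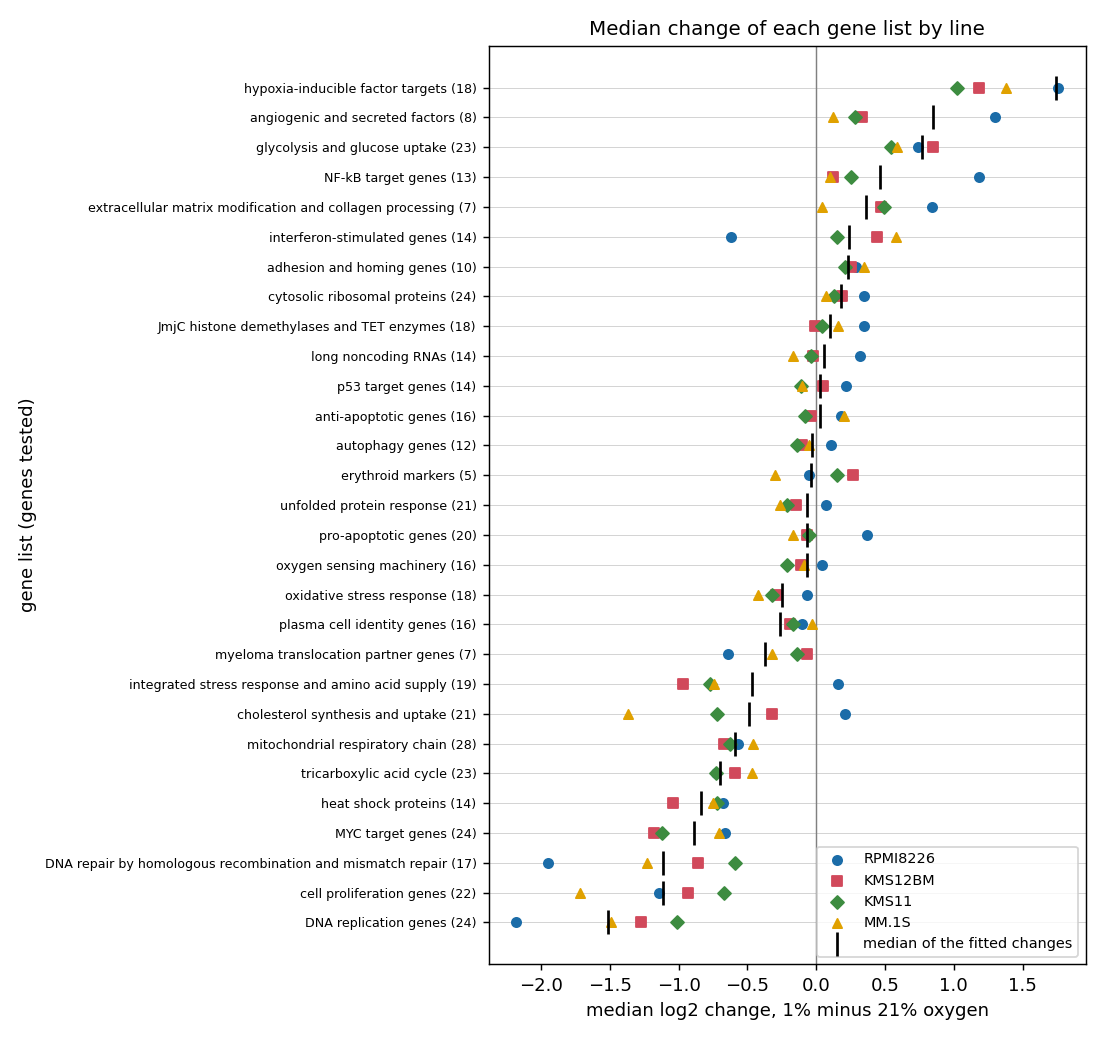
Median log2 change between 1% and 21% oxygen (x axis) of the tested genes of each list (y axis, number of genes tested in brackets). Points are the 4 lines and black bars the medians of the fitted changes, from -1.51 for DNA replication genes to 1.74 for hypoxia-inducible factor targets.

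Markers of other cell types were few and mostly not called. Tested members numbered 3 for T and NK cells, 3 for monocytes and macrophages, 2 for stroma and endothelium, 5 for the erythroid lineage and 4 for less mature B cells. Of these, only TAGLN, a stromal marker, was called, also over the list alone (1.64-fold higher, SE 0.18, adjusted p = 0.033), and that call ended without KMS12BM, KMS11 or MM.1S and under quantile normalization. The erythroid list did not pass the camera test (adjusted p = 0.51).

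Genes activated by myeloma translocations differed between lines. FGFR3 was at 8.66 on the normalised log2 scale in KMS11 and between -4.48 and -1.14 in the other lines (means of 2 arrays), and NSD2 was at 4.00 in KMS11 against 0.76 to 2.32 elsewhere. In RPMI8226 and in MM.1S, FGFR3 was well above background on only 1 of the 2 arrays. CCND1 was at 2.72 in KMS12BM and not well above background in KMS11. CCND2 was not well above background in KMS12BM and lay between 4.87 and 5.53 in the other lines, and MAF was at -1.75 in KMS12BM against 5.31 to 6.53. Of 7 tested genes of this list, NSD2 was called lower under hypoxia (1.81-fold lower, SE 0.20, adjusted p = 0.026; 2 of its 4 tested probes were not called, with log2 changes of -0.72 and -0.36), a call that ended without RPMI8226, KMS12BM or MM.1S and under quantile normalization (1 higher and 2 lower over the list alone; camera adjusted p = 0.69). Lines accounted for 82.6% of the variance over tested probes and oxygen for 10.9%.

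Within single lines, where no replicate allowed a test, the number of probes at least 2-fold higher under hypoxia was 950 in RPMI8226, 1108 in KMS12BM, 1244 in KMS11 and 1012 in MM.1S. The number at least 2-fold lower was 1797, 1456, 1354 and 1606 in the same order, out of 19556 probes measured on all arrays. All 4 lines shared 90 probes that were 2-fold higher and 156 that were 2-fold lower, where independent lists would share 0.18 and 0.76. Across probes, which are not independent replicates, the log2 changes of 2 lines correlated with Pearson's r between 0.387 (KMS11 and MM.1S; Spearman's rho 0.441) and 0.691 (KMS12BM and KMS11; rho 0.726) over the 6 pairs of lines. After normexp background correction of the median spot signals with an offset of 50, 23 probes were 2-fold higher in all 4 lines, and 342 to 611 by line (946 lower in MM.1S). With only probes well above background on all 8 arrays, 57 were higher in all 4 lines and 647 in MM.1S. Quantile normalization left 79 probes and median centring 90 that were 2-fold lower in all 4 lines. With no filter, 201 were higher in all 4 lines, 4327 to 16076 higher and 2737 to 4236 lower by line, and the mean r between lines was 0.19 against 0.50.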

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

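Of the tests in this part, those of slide row, of scaling, of fewer cycling cells, of a compressed signal range and of an array swap were chosen only after the result was seen. A value stood apart from the other 3 of its group in 17 of 182 groups of 4 checked, and chance alone sets about 1 in 20 apart.

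Single lines stood apart for several genes. In RPMI8226 the log2 change was 3.77 for HILPDA, 2.13 for CIITA, 1.57 for BIRC3, -2.29 for MCM2 and -0.65 for SHMT2. In MM.1S it was 2.24 for EGLN1, -0.88 for DLAT, -0.68 for FH, -1.22 for CS and -0.06 for COL4A2. In KMS12BM it was 1.90 for COL4A1. Levels stood apart for CCND2 in KMS12BM (-6.39 under normoxia and -5.44 under hypoxia), MAF in KMS12BM (-1.71 and -1.78) and FGFR3 in KMS11 under normoxia (8.65). The median processed signal of the MM.1S normoxia array was 25.99, below the other 3.

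Among the 160 named genes checked, lines went opposite ways by at least 1.5-fold each for 4, and the difference was not tested. Over all probes measured on all arrays, 249 were 2-fold higher in 1 line or more and 2-fold lower in another. CIITA changed by -0.71 in KMS11 and 2.13 in RPMI8226, XAF1 by -0.80 in RPMI8226 and 1.65 in MM.1S, TYROBP by -1.34 in MM.1S and 0.75 in KMS11, and EPOR by -0.72 in MM.1S and 0.60 in KMS12BM.

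For the fall of DNA replication genes another scaling is argued against, since the median of the list stayed at -1.39 or lower under median centring, quantile normalization and normexp correction. Lower signal on the hypoxia arrays is argued against too, since random lists matched on mean signal had a median of -0.27 and 0 of 10000 reached the list. A slide row effect stays open: the median was -1.48 with row as a term, but by the file headers MM.1S alone separates row from oxygen. By the file names row and oxygen cannot be told apart. Fewer cells in cycle at 1% oxygen stays open as a hypothesis: replication and proliferation lists were at -0.67 or lower in each line, and expression of bulk cells does not separate fewer cycling cells from lower expression per cell.

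More probes were called lower than higher. The percent of calls that were higher was 29.6, and reached 44.4 under median centring, which leaves open how much of the imbalance comes from scaling. Dim probes losing signal on the hypoxia arrays is argued against, since 12.6% of calls were higher among the brightest 6526 probes and 57.9% among the dimmest 6526. A compressed range of signal on the hypoxia arrays is a candidate explanation: the median change of the brightest probes minus that of the dimmest was -0.35, and 39.2% of calls were higher after quantile normalization. The -0.35 comes from the same changes as the calls, so it cannot decide the question. The mean ratio of hypoxia to normoxia signal was 0.843 at the median, but 0.663 at both the 75th and the 99th percentile. The range was thus not narrower between these 2 percentiles. Random lists matched on signal to ribosomal protein genes had a median change of 0.19. A change of the cells at 1% oxygen stays open too and was not tested.

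The slide positions in the headers of both MM.1S files are the reverse of those in the file names, unlike in the other 3 lines. A swap of the 2 arrays between the oxygen groups is argued against, since the hypoxia-inducible factor targets had a median change of 1.38 in MM.1S under the labels as given, in the direction of the other 3 lines (1.02 to 1.76). No biological explanation was tested.

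Of the 35 splits of the arrays into 4 and 4, 8 part every line, too few for a share under 0.05. The real one called 4523 probes and the highest of the other 7 called 0 (1 of 8 as large). It put 16 lists past the camera test with a preset correlation, and another put 17 (2 of 8 as large). The split with 17 exchanged the arrays of KMS11 alone, so it was not free of oxygen. Splits that part every line and were balanced for oxygen put 4 to 7 lists past the test. The splits that part 2 lines (24) called at most 0 probes and put up to 18 lists past the test. With line as a block, such a split rests on the 2 parted lines alone. Where both were parted by oxygen in the same direction, 12 to 18 lists passed. Where they were parted in opposite directions, 0 to 7 passed. A further 3 splits could not be fitted.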

How the results depend on the processing

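Slide row as a term was chosen only after the data were seen; the other settings were fixed before. Signal over background limits how many probes could be tested: 42.52% to 52.99% were well above background on an array. With no filter no probe was called (0 higher, 0 lower, 0 at least 2-fold either way), and limma gave 8894 of 50550 at an unadjusted p under 0.05; the cause was not tested. With no replicate block, so without the cell line pairing, the counts were also 0, 0, 0 and 0 (1450 at an unadjusted p under 0.05), as the differences between lines then enter the error. Leaving out each line in turn gave 241 to 844 higher and 560 to 2043 lower probes (232 to 483 and 536 to 894 at least 2-fold), with fewer samples in each fit. Slide row as a term gave 819 and 1789, quantile normalization 1727 lower (577 at least 2-fold), median centring 589 lower at least 2-fold and normexp correction 186 higher at least 2-fold. With 1 probe per gene, which tests fewer probes, 664 were higher (213 at least 2-fold). Of 106 named genes called, 52 were called without any 1 line, 51 of them also under every other setting but no filter and no block, and none changed sign under the settings run. Quantile normalization ended 17 of these calls, slide row 22, and the removal of replicates 1 to 4 ended 22, 48, 36 and 21. No gene list passed camera with an estimated correlation (0, against 16). That version takes its p-values from the 3 residual degrees of freedom, the preset one from the number of genes. It thus has far less power. How much of the loss comes from this was not tested. For glycolysis, matrix and adhesion genes the estimates (-0.002, -0.078 and -0.109) lay below the preset 0.01. A higher correlation is thus argued against as the cause for these lists. For the other lists that passed with the preset value, the estimate lay above it.

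Within lines, normexp correction left 23 probes 2-fold higher in all 4 lines, 489, 492, 611 and 342 higher in RPMI8226, KMS12BM, KMS11 and MM.1S, and 946 lower in MM.1S. Its offset of 50 lay above the median processed signal of each array (25.99 to 40.20). Such an offset by itself shrinks the log2 changes of dim probes. How much of the drop comes from it was not tested. Quantile normalization left 79 and median centring 90 that were 2-fold lower in all 4 lines, with the cause not tested. With no filter, which admits dim probes, 201 were 2-fold higher in all 4 lines, 6127, 9650, 16076 and 4327 higher and 3324, 2737, 2979 and 4236 lower by line, and the mean correlation between lines was 0.19. The filter on all 8 arrays, which tests fewer probes, left 57 higher in all 4 lines and 647 higher in MM.1S.

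The direction that camera gives turned for 7 lists that did not pass the test. That direction is relative to the other genes. With no filter the median log2 change of all probes was 0.244, against -0.074 in the main fit, so lists near 0 then lay below most others. For the other settings the cause was not tested. Values in brackets are the medians under the setting, which need not change sign with camera's direction. With no filter camera's direction turned for oxygen sensing (-0.07), anti-apoptotic (0.03), pro-apoptotic (0.00), unfolded protein response (-0.07) and erythroid genes (-0.04) and long noncoding RNAs (0.04). For the unfolded protein response it also turned after normexp correction (-0.17), with array weights (-0.08), with slide row (-0.13) and among fits without 1 line (-0.20 to 0.05). For plasma cell genes camera's direction turned under quantile normalization (-0.09), with no replicate block (-0.26), with slide row (-0.24) and among fits without 1 line (-0.26 to -0.15), while every median stayed below 0. Among genes not called, log2 changes turned for CIITA with array weights (-0.24), slide row (-0.15) and without 1 line (-0.64 to 0.31). Quantile normalization turned CD4 (0.08), CD33 (0.00) and CD14 (-0.07). Array weights turned CD14 (-0.07), TYROBP (0.21) and EPOR (0.08), and normexp correction TYROBP (0.08), CDH5 (0.10) and EPOR (0.01). Median centring turned TYROBP (0.08), CDH5 (0.00) and EPOR (0.01). Without 1 line the range was -0.10 to 0.33 for CD3D, -0.05 to 0.16 for CD14, -0.28 to 0.42 for TYROBP and -0.33 to 0.12 for EPOR.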

Other observations

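MINDY4, a deubiquitinase, was well above background on all 4 normoxia arrays and on none under hypoxia, at least 1.88-fold lower (adjusted p = 0.0081), a call that ended after normexp correction (log2 change -0.29). BCL2L10, an anti-apoptotic gene that was not tested, was well above background on 0 normoxia arrays and 2 hypoxia arrays, at least 1.77-fold higher; it was picked out after its values were seen. BNIP3, a mitophagy gene and standard target of the hypoxia-inducible factors, was well above background in RPMI8226 and KMS11 alone, with log2 changes of 0.49 and 1.20, while its relative BNIP3L rose in all 4 lines.

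ADM, a vasodilator peptide, had log2 changes of 2.50 in RPMI8226, 1.08 in KMS12BM, 3.63 in KMS11 and -0.17 in MM.1S (adjusted p = 0.059). EGLN3, well above background in RPMI8226 alone, had a log2 change of 1.40 there. FAS, a death receptor, was 1.65-fold lower (SE 0.16, adjusted p = 0.023), and that call ended without any 1 of the 4 lines and with slide row as a term.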
